A study of Mus musculus with 30 samples.

How the data were processed

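Polyadenylated RNA of 28 cortical tumours and 2 normal cortex samples of mice at postnatal day 70 had been sequenced from stranded libraries. The deposited tables give 1 signal per gene and library, which the authors made from gene read counts by dividing by 1 size factor per library. That was tested on the values: all but 1 value came to a whole number of reads within 0.05 of a read once a constant per library was removed (at least 99.9944% of the values of each library). The median ratio to the geometric mean over all libraries was 1.00184 in every library, as DESeq2 size factors from 1 run over all 30 libraries give. The tables are named RPM, and the design was fixed on that assumption, but the library totals were 9.31187 to 12.036 times what RPM sum to, so the values were size-factor-normalised counts. They were divided by the mean of these ratios, 10.2638, the same for every library, and the result is called RPM. The submitters name FastQC, STAR 2.5.0a, the mm10 genome and DESeq2 1.20.0 without their roles.

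The 9 tables listed the same 24421 genes, of which 3274 had no read in any library and none was of the mitochondrial genome. A spreadsheet had turned 27 gene names into dates, 2 of which stood for 2 genes each. These genes were kept under the names given. The recovered reads, 2784129 to 24475215 per library, set the precision: 1 read was 0.0387 to 0.383 RPM, and exact Poisson 95% intervals are given for single libraries. Positions came from GENCODE release M21 on mm10, which held 15233 of the tested genes (96.3%).

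The 15824 genes with at least 1 RPM in at least 3 libraries were tested. On log2(RPM + 1), limma 3.58.1 in R 4.3.3 fitted 9 group means to all 30 libraries (eBayes with trend and robust, 21 residual degrees of freedom, two-sided). The adjusted p is that of Benjamini and Hochberg within a comparison (threshold 0.05). The 16 pairs compared were mCherry with cortex, each receptor form with mCherry, each variant with wild-type EGFR, A289I with A289V and R108G with R108K. An F-test sought any difference among the 8 tumour groups. On simulated data (200 of 15824 genes changed) the fit recovered 74% to 85% of 8-fold and 31% to 47% of 2.8-fold changes, with 4 to 8 false calls among 113 to 136, none of wrong sign, by comparison. Regrouped real libraries gave up to 1733 calls, so real rates may differ.

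The design, the 28 gene lists and the rule for the named genes were fixed before the data were examined. A list of mitochondrial transcripts had no gene in the tables and could not be tested, which left 27 lists. They were tested with camera at its preset correlation of 0.01, adjusted over 432 tests, and again with an estimated correlation and with fry. Of the 137 calls, none held with an estimated correlation and 19 held in fry, which passed 20. No list's median or mean differed in sign from its call. The rule named, among passing genes whose groups did not overlap and with a mean of at least 5 RPM in the higher group, the 8 largest rises and 8 largest falls, or the 3 smallest p of each direction where none passed. It named up to 4 members of each passing list, Egfr always, and the 20 smallest p of the F-test. Predicted loci, Xist, Tsix and 4 Y-linked genes were passed over, other X-linked genes were not. After the results were seen, the description was limited to the 4 lists of lowest p and 3 members each in a comparison, and to 6 lists and 4 members for mCherry against cortex. Every list that passed is counted.

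The alternatives chosen before the values were seen were a pseudocount of 0.1 RPM, no filter, a filter of 5 RPM, TMM rescaling, library weights, a term for 2 ranges of library numbers (to 37, and above), only the groups compared, and each library left out in turn. The recovered reads were also tested with edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 (Wald). Chosen after seeing the data were a term for 3 ranges, groups compared within 1 range, the 3 libraries with Met above 1000 RPM left out, R108G libraries 1 and 3 left out, A289V libraries 1 and 2 left out, and the mean of the neuron list as a covariate with its genes left out of the test. Within a range, a group of 1 library was assumed to vary like the other groups. Labels were regrouped in up to 100 splits. Neighbouring genes were scanned in windows of 7 among 10791 genes with a mean of at least 10 RPM, for a median of at least 1.5 above the tumour median on the log2 scale. Checks and figures used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.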

Results

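Polyadenylated RNA of 28 mouse brain tumours and 2 samples of normal cortex was sequenced at postnatal day 70, with 1 library per sample. The tumours had been given mCherry, a fluorescent control protein, or the epidermal growth factor receptor EGFR as the wild-type form or as 1 of 6 forms with a single amino acid change. The groups held 3 mCherry libraries, 3 EGFR wild-type libraries, 5 A289I, 4 A289V, 3 R108G, 4 R108K, 3 R222C, 3 T263P and 2 normal cortex libraries. Levels are given as RPM, here the deposited normalised count divided by 10.2638. Of the 24421 genes listed, 15824 passed the filter on low values. The library numbers fell in 3 ranges, below 20, 20 to 37, and above 37. The share of reads from the ribosomal RNA gene Rn45s was 2.47% to 4.57% in the 12 tumours of the range 20 to 37, 0.165% to 0.343% in the 7 tumours below 20 and 0.117% to 1.32% in the 9 tumours above 37. All A289I and R108G libraries carried numbers above 37, and all R222C, T263P and cortex libraries numbers from 20 to 37.

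Egfr, the receptor gene itself (mm10 chromosome 11, 16752203 to 16918158), was measured in every library to ask how much receptor transcript each tumour carried. The labels do not say whether the introduced receptor had the mouse or the human sequence, so the mouse gene was the nearest readout. Egfr was 12.02 ± 0.995 RPM in normal cortex (SD, n = 2) and 29.4 ± 6.78 RPM in mCherry tumours (n = 3). It was 239 ± 141 RPM in EGFR wild-type tumours (n = 3), 557 ± 130 RPM in A289I tumours (n = 5), 270.4 ± 221 RPM in A289V tumours (n = 4) and 319 ± 221.8 RPM in R108K tumours (n = 4). The spread was wider in R108G tumours (267 ± 403 RPM, n = 3), R222C tumours (1058 ± 1503 RPM, n = 3) and T263P tumours (392 ± 478 RPM, n = 3). R108G libraries 1 and 3 had 17.5 RPM (exact Poisson 95% interval 15.7 to 19.4) and 52.3 RPM (48.7 to 56.1), against 22.1 to 35.4 RPM in the mCherry tumours and 732 RPM in R108G library 2. T263P library 2 was as low, at 52.1 RPM (47.1 to 57.5). The highest level was 2790 RPM in R222C library 3 (2760 to 2820). These intervals cover counting error only. The limma test of Egfr against mCherry passed in 1 of the 7 comparisons, A289I, where the log2 fold change was 4.19 ± 0.98 (SE, adjusted p = 0.0461). That call was lost in 14 of 21 alternatives, among them the removal of any 1 of the 8 libraries compared. Over all alternatives its adjusted p was at most 0.389, and DESeq2 called Egfr in 4 of the 7 comparisons.

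**Figure D1:**
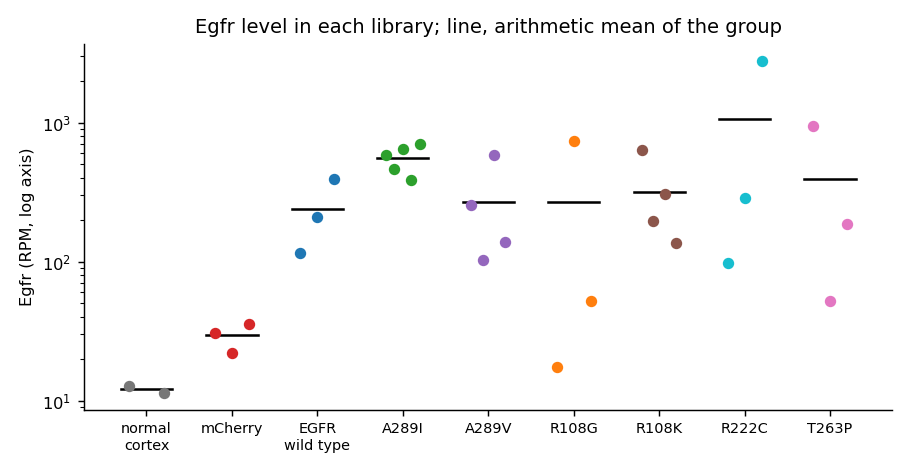
Egfr level in RPM on a log axis, 1 point per library, by group, with a line at the arithmetic mean of each group. R108G library 1 (17.5 RPM) lay below the mCherry tumours.

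Control tumours were compared with normal cortex to ask what sets a tumour without added receptor apart from the tissue it grew in. Genes of cell division, interferon response and antigen presentation were far higher in the mCherry tumours, and genes of neurons and myelin far lower. Cdkn2a, which encodes inhibitors of the cell cycle, was 326 ± 382 RPM in the tumours (n = 3) and 0.424 ± 0.600 RPM in cortex (n = 2), and Top2a, a topoisomerase of dividing cells, was 273 ± 92.2 against 1.45 ± 0.349 RPM. In all, 2815 genes rose and 3246 fell, and 5079 of these 6061 genes changed at least 2-fold. The largest rises by the naming rule were Cdkn2a (log2 fold change 7.24 ± 0.74 SE, adjusted p = 2.1e-07), Gpnmb (7.04), the chemokine Cxcl10 (6.92), Top2a (6.76 ± 0.54, adjusted p = 1.51e-08), the interferon-induced GTPases Tgtp2 (6.76), Tgtp1 (6.67) and Iigp1 (6.62), and the guanylate-binding protein Gbp10 (6.61). The largest falls were in Lamp5 (-5.35 ± 1.07, adjusted p = 0.000508), the prostaglandin synthase Ptgds (-4.79), the myelin genes Opalin (-4.77), Mal (-4.62) and Mobp (-4.51), the GABA receptor subunit Gabrd (-4.65), the neuronal calcium sensor Vsnl1 (-4.60) and C1qtnf4 (-4.60).

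Of the 30 cell cycle genes, 29 rose over all genes and all 30 when adjusted over the list alone, among them Cdk1 (5.66), Ube2c (5.09) and Bub1b (5.40). Of 20 interferon response genes, 19 rose and 20 did when adjusted over the list alone, with Bst2 at 5.58, Usp18 at 5.14, Isg15 at 6.23 and Gbp3 at 5.81. Of 13 antigen presentation genes, 12 rose by either count, with B2m at 3.91, Nlrc5 at 5.95, Psmb8 at 5.29 and H2-D1 at 5.06. Of 20 genes of the mesenchymal glioma list, 11 rose and 12 did when adjusted over the list alone, with Vim at 4.95, Stat3 at 2.57 and S100a11 at 2.26. Of 25 neuron genes, 22 fell and 24 did when adjusted over the list alone, with Vip at -4.25, Slc17a6 at -3.62, Eno2 at -3.40 and Pvalb at -4.33. Of 16 genes of myelinating oligodendrocytes, 10 fell and 12 did when adjusted over the list alone, with Mog at -4.44 and Mbp at -3.96. The camera adjusted p of these 6 lists ran from 3.24e-29 for cell cycle to 7.45e-05 for the mesenchymal list, and the adjusted p was 0.802 to 0.842 with estimated correlation, so that none held. In all, 14 of 27 lists passed, 10 up and 4 down. No range of library numbers held both groups, and the count was 3867 with a term for the 3 ranges, 3444 and 3280 without cortex library 1 or 2, and 1662 with the mean of the neuron list as a covariate. That covariate also ended the calls of 6 of the 33 named genes left to test, and the cell cycle, interferon and antigen presentation lists kept their calls under it.

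Wild-type EGFR was compared with mCherry to ask what the unaltered receptor adds. Met, a receptor tyrosine kinase gene (mm10 chromosome 6, 17463800 to 17573980), was 4610 and 3853 RPM in EGFR wild-type libraries 1 and 2 and 6283 RPM in mCherry library 2, against at most 437 RPM in any other tumour. Neu4, a sialidase gene of the oligodendrocyte precursor (OPC) list (mm10 chromosome 1, 94020451 to 94028334), was 21.7 ± 14.6 RPM with the wild-type receptor and 4.10 ± 2.43 RPM with mCherry (n = 3 each), a log2 difference of 2.06 ± 0.49 that did not pass (limma adjusted p = 1). S100a1, a calcium-binding protein gene, was 149 ± 46.4 against 42.6 ± 20.1 RPM and Efcab1 3.93 ± 0.856 against 0.958 ± 1.12. Map7 was 18.8 ± 1.54 against 46.7 ± 2.70 RPM, Pcdhb4 1.03 ± 0.145 against 5.70 ± 4.16 and Kat6b 19.6 ± 3.31 against 43.9 ± 7.76. No gene passed with limma, 428 had an unadjusted p under 0.05, edgeR gave 0 and DESeq2 10. Egfr did not pass with limma (115 to 393 against 22.1 to 35.4 RPM), so no call does not mean no difference.

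Of 27 lists, 5 passed. All 25 neuron genes had lower means with wild-type EGFR (camera adjusted p = 3.34e-06), such as Nefm at -1.75, Nefl at -1.58 and Slc17a6 at -1.21 on the log2 scale. Of the myelin genes, 13 of 16 had higher means (adjusted p = 0.00488), such as Cnp at 1.05, Cldn11 at 0.90 and Ugt8a at 0.91. Cell cycle genes lay higher in 26 of 30 (adjusted p = 0.00788), such as Cenpf at 0.62, Mcm3 at 0.52 and Ccnb1 at 0.59, and interferon genes lower in 19 of 20 (adjusted p = 0.008), such as Oas2 at -1.71, Oasl2 at -1.20 and Ifi44 at -1.17. No member of these 4 lists passed over all genes or adjusted over the list alone, and their adjusted p was 0.842 to 0.903 with estimated correlation. Within library numbers below 20 (2 libraries against 2) 1 gene passed, as did 1 without mCherry library 2. Without the 3 libraries with high Met, EGFR wild-type library 3 stood alone against 2 and the cell cycle list reversed. Wherever a group was left with 1 library, the other groups gave the spread, and the result describes that 1 tumour. Single libraries ended list calls. The interferon list reversed without EGFR wild-type library 3 (adjusted p = 0.306) and was lost without mCherry library 2 (0.277) or 3 (0.149), with a term for 2 or 3 ranges (0.146 and 0.461), library weights (0.489) or DESeq2 (0.159). The neuron list was lost without EGFR wild-type library 2 (0.244) or mCherry library 1 (0.271), and the cell cycle list without EGFR wild-type library 1 (0.156) or 2 (0.122) or mCherry library 2 (0.554), with library weights (0.0553) or the neuron covariate (0.578). The myelin list was lost without EGFR wild-type library 3 (0.0575), mCherry library 2 (0.552) or the high Met libraries (0.346) and with library weights (0.0981).

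**Figure D2:**
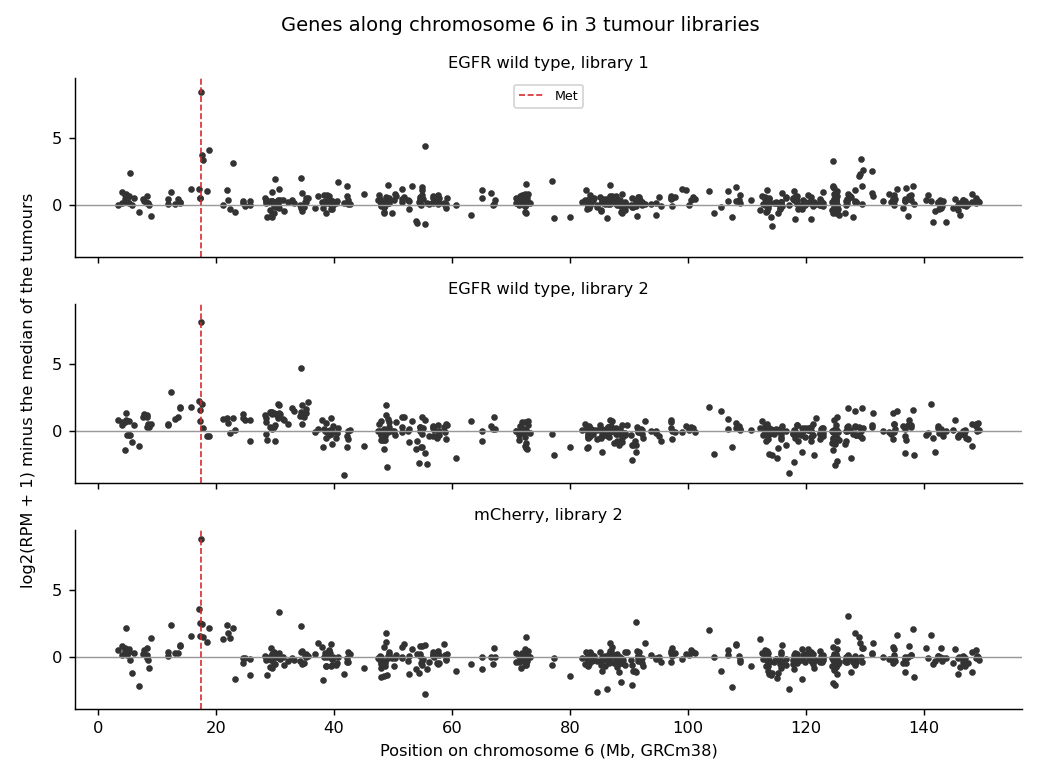
Genes along chromosome 6 (position in Mb) in 3 tumour libraries, each as log2(RPM + 1) minus the median of the tumours, with a dashed line at Met. Met stood far above 0 in EGFR wild-type libraries 1 and 2 and mCherry library 2.

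The A289I form, changed at an alanine of the receptor's extracellular part, was compared with mCherry to ask what it adds over the control protein. Neu4 rose from 4.10 ± 2.43 RPM in mCherry tumours (n = 3) to 98.0 ± 38.0 RPM (n = 5), and the myelin gene Mag from 32.6 ± 21.8 to 525 ± 209 RPM. Myrf, which encodes a transcription factor of myelin genes, rose from 29.3 ± 3.45 to 276 ± 55.4 RPM. In all, 83 genes rose and 13 fell, and 94 of the 96 changed at least 2-fold. The largest rises were Neu4 (log2 4.31 ± 0.44 SE, limma adjusted p = 6.25e-06), Mag (4.23 ± 0.77, adjusted p = 0.0225), Egfr, Dct, a melanin synthesis enzyme (3.75), Mog (3.58), Tmem163 (3.38), Myrf (3.18) and the collagen gene Col9a3 (3.17). The largest falls were Sectm1a (-2.84 ± 0.63, adjusted p = 0.0376), Kank4os (-2.13), Fnbp1l (-1.51), Etaa1 (-1.32), Sh3bgrl (-1.32), the actin-binding thymosin gene Tmsb4x (-1.27), Wbp5 (-1.26) and Zc4h2 (-1.18).

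Of the 16 genes of myelinating oligodendrocytes, 7 rose and 13 did when adjusted over the list alone (camera adjusted p = 1.07e-19, 0.749 with estimated correlation). Of 17 OPC genes, 2 rose, Neu4 and Gpr17 (2.56), and 6 did when adjusted over the list alone, while Bcan was at 1.504 with an adjusted p of 0.117 (list adjusted p = 6.48e-05, 0.839 with estimated correlation). Of 18 astrocyte genes, 1 rose by either count, Aldoc (1.42), with Atp1b2 at 0.88 and S100b at 1.23 (list adjusted p = 0.000213, 0.842 with estimated correlation). None of the 30 cell cycle genes passed, over all genes or adjusted over the list alone, and 28 had lower means, such as Tyms at -0.96, Mcm7 at -0.88 and Cdk1 at -0.81 (list adjusted p = 0.000372, 0.878 with estimated correlation). In all, 9 of 27 lists passed. Leaving out any 1 of the 8 libraries moved the gene count by over 1.5 times, to 162, 3, 27, 1 and 32 without A289I libraries 1 to 5 and to 38, 10 and 1 without mCherry libraries 1 to 3. It was 1 with edgeR, 349 with DESeq2, 16 with a term for 2 ranges of library numbers (4 up, 12 down), 21 within the range above 37 (5 libraries against 1, 4 up and 17 down) and 21 without the high Met libraries (10 up, 11 down). Of the 18 named genes called, 3, 3 and 4 kept their call in these settings. Neu4 passed in all 21 alternatives, with an adjusted p of at most 0.00402, whereas the OPC and astrocyte lists were lost without mCherry library 2 (adjusted p = 0.059 and 0.0922) or without the high Met libraries (0.06 and 0.0938), the OPC list with a term for 2 or 3 ranges (0.114 and 0.121) and the cell cycle list without mCherry library 3 (0.0955).

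**Figure D3:**
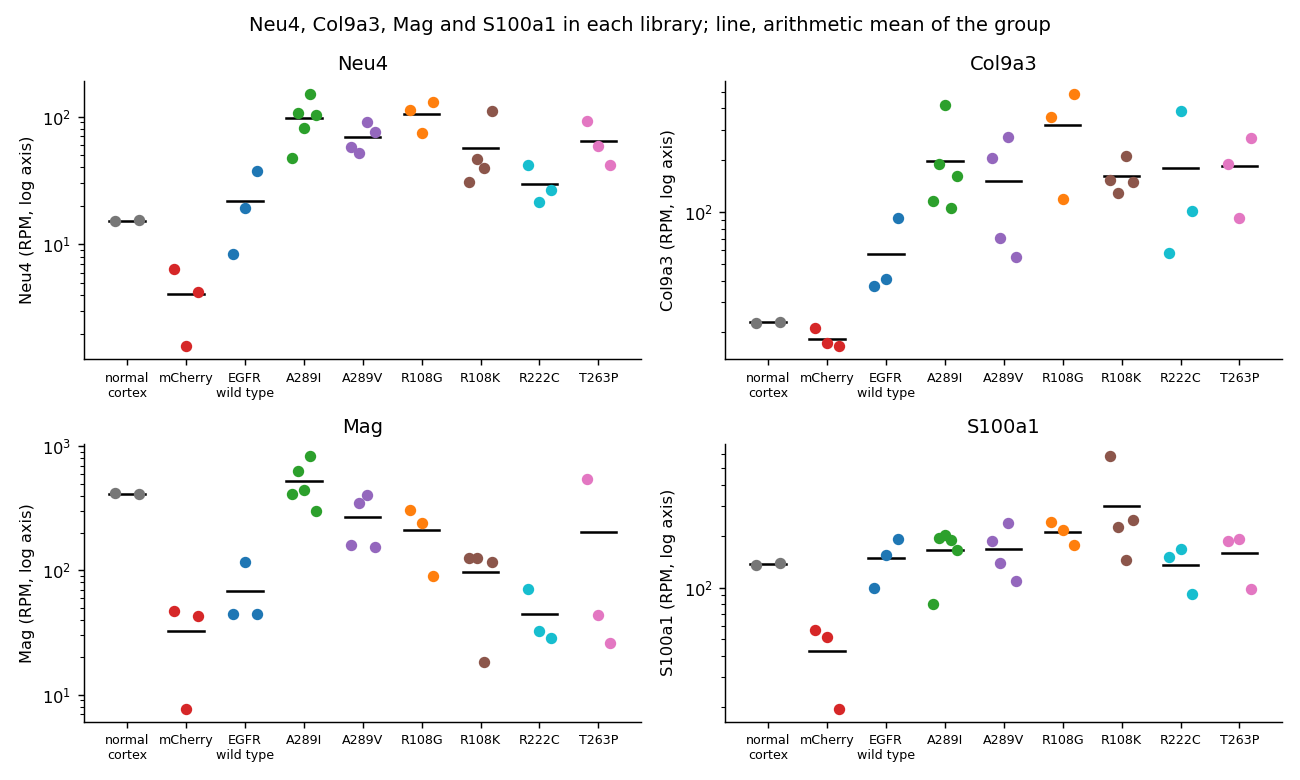
Neu4, Col9a3, Mag and S100a1 in RPM on log axes, 1 point per library, by group, with a line at the arithmetic mean. Neu4 lay between 1.59 and 6.44 RPM in the mCherry tumours and between 47.3 and 151 RPM in the A289I tumours.

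A289V, the other change at the same alanine, was compared with mCherry for the same question. Neu4 rose to 68.9 ± 17.9 RPM (n = 4) and S100a10, the binding partner of an annexin, fell from 143 ± 14.5 RPM with mCherry (n = 3) to 30.3 ± 7.28 RPM. In all, 511 genes rose and 266 fell, and 628 of these 777 changed at least 2-fold. The largest rises were Cdr1 (log2 3.95 ± 0.94 SE, limma adjusted p = 0.0332), Neu4 (3.87 ± 0.46, adjusted p = 0.000123), the sulfotransferase gene Hs3st2 (3.27), Mag (3.22), chromogranin A, Chga (3.21), Dct (3.09), the troponin gene Tnnc1 (3.00) and Fam163b (2.94). The largest falls were Sectm1a (-3.02), Fam60a (-2.85), the basement membrane collagen gene Col4a5 (-2.51), Tex19.1 (-2.48), Dach2 (-2.39), the myeloid receptor gene Clec7a (-2.38), S100a10 (-2.23 ± 0.37, adjusted p = 0.0141) and Cdkn2a (-2.16). Egfr was at 2.85 ± 1.02 with an adjusted p of 0.0891.

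Of the 25 neuron genes, 3 rose over all genes, Eno2 (2.11), Syn2 (2.21) and Syn1 (2.07), and 20 did when adjusted over the list alone (camera adjusted p = 4.62e-09, 0.842 with estimated correlation). The mean of this list, on log2(RPM + 1), was 7.79, 8.10, 6.26 and 6.45 in A289V libraries 1 to 4, against 4.27 to 6.39 in the mCherry tumours and 8.47 and 8.48 in cortex. Of 30 cell cycle genes, 1 fell, Nusap1 (-1.23), and 13 did when adjusted over the list alone, with Mcm7 at -1.28 and Pcna at -0.80 (adjusted p = 1.19e-09, 0.842 with estimated correlation). Of 16 myelin genes, 3 rose, Mag, Mal (2.48) and Mog (2.79), and 12 did when adjusted over the list alone (adjusted p = 4.74e-07, 0.802 with estimated correlation). Of 16 cholesterol synthesis genes, 2 rose, among them Hmgcs1 (1.24), and 8 did when adjusted over the list alone, with the regulator Srebf2 at 0.88 (adjusted p = 1.77e-05, 0.802 with estimated correlation). In all, 10 of 27 lists passed. The gene count fell to 3 without A289V library 1 or 2, 2 without mCherry library 3 and 104 without mCherry library 2 (22 up, 82 down), and was 1674 without A289V library 4 and 1316 without mCherry library 1. It was lower with edgeR and 1729 with DESeq2, 2 with a term for 2 ranges, 2 within library numbers below 20 (1 library against 2), 1 with the neuron covariate, 1 without A289V libraries 1 and 2, and 46 without the high Met libraries (6 up, 40 down).

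**Figure D4:**
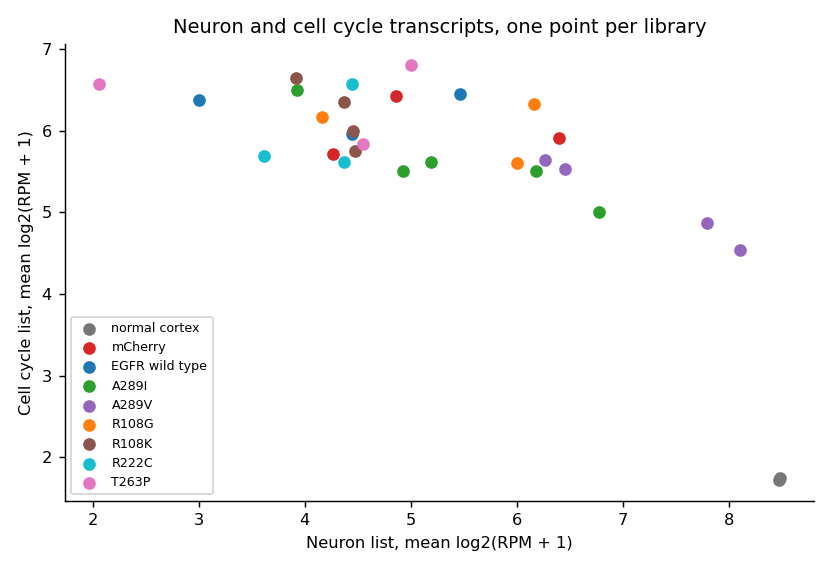
Mean of the cell cycle list against the mean of the neuron list, each on log2(RPM + 1), 1 point per library, coloured by group. A289V libraries 1 and 2 (neuron means 7.79 and 8.10) lay between the other tumours and the 2 cortex libraries (8.47 and 8.48).

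R108G, changed at an arginine of the extracellular part, was compared with mCherry likewise. Neu4 rose to 105.5 ± 27.8 RPM (n = 3, log2 4.48 ± 0.49 SE, limma adjusted p = 2.72e-05). Col9a3 rose from 18.4 ± 2.51 to 321 ± 186 RPM (3.84 ± 0.64, adjusted p = 0.0169) and S100a1 from 42.6 ± 20.1 to 213 ± 32.9 RPM (2.42, adjusted p = 0.0387). Oraov1 (1.54) and Ppfia1 (1.36) rose too, both highest in R108G library 3 (99.6 and 295 RPM). Ppfia1 lay there in a raised run of 8 genes with the cyclin gene Ccnd1 (chromosome 7, median log2 2.01). In all, 6 genes rose and none fell with limma, while 1330 had an unadjusted p under 0.05, edgeR gave 6 and DESeq2 98. Egfr was at 1.59 ± 1.09 with an adjusted p of 0.739.

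Among the lists, 10 of 27 passed. Of 16 myelin genes, none passed over all genes and 4 rose when adjusted over the list alone, with Opalin at 2.85, Mag at 2.85 and Myrf at 2.07 (camera adjusted p = 5.29e-07, 0.802 with estimated correlation). Of 17 genes of endothelium and pericytes, none passed over all genes and 2 did when adjusted over the list alone, with Vwf at 1.63, Esam at 0.996 and Pdgfrb at 0.87 (adjusted p = 1.02e-06, 0.802 with estimated correlation). Of 16 T and NK cell genes, none passed by either count and 15 had higher means, with Cd5 at 1.499, Cd3e at 1.64 and Cd2 at 1.30 (adjusted p = 2.21e-05, 0.842 with estimated correlation). Of 6 B and plasma cell genes, none passed over all genes and 4 rose when adjusted over the list alone, with Cd79b at 1.61 and Cd79a at 2.12 (adjusted p = 2.24e-05, 0.802 with estimated correlation). The gene count was 10 and 1 without R108G library 1 or 3, 2 without mCherry library 3, 0 with only these groups in the fit (1123 at an unadjusted p under 0.05), 10 with a term for 2 ranges (2 up, 8 down), 15 within the range above 37 (3 libraries against 1, 2 up and 13 down), 13 without R108G libraries 1 and 3 (1 against 3), and 14 without the high Met libraries. Neu4 passed in 19 of 20 alternatives, the exception being the fit of only these groups (adjusted p = 0.0782), and the vessel, T and NK and B cell lists were lost with the 2-range term (adjusted p = 0.228, 0.088 and 0.117) and the 3-range term (0.221, 0.0994 and 0.127).

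R108K, the other change at that arginine, was compared with mCherry likewise. Neu4 rose to 56.8 ± 36.3 RPM (n = 4, log2 3.46 ± 0.46 SE, limma adjusted p = 0.000985) and S100a1 to 301 ± 194 RPM (2.74 ± 0.42, adjusted p = 0.00584). Bfsp2, an intermediate filament gene best known from the lens, rose from 10.9 ± 2.54 RPM to 163 ± 53.3 RPM (3.74 ± 0.62, adjusted p = 0.0154). In all, 8 genes rose and 3 fell. The other rises were Acacb, an acetyl-CoA carboxylase (3.38), Col9a3 (3.04), the myelin protein gene Pllp (2.8), Efcab1 (1.88) and Prr14 (0.98). The falls were the fatty acid elongase gene Elovl2 (-2.46 ± 0.44, adjusted p = 0.0277), the teneurin gene Tenm3 (-1.68) and the ephrin gene Efnb1 (-1.46). Egfr was at 3.18 ± 1.02 with an adjusted p of 0.284.

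Of 27 lists, 12 passed here. Of 6 B and plasma cell genes, none passed over all genes and 4 rose when adjusted over the list alone, with Cd79b at 1.63, Cd79a at 2.17 and Mzb1 at 3.08 (camera adjusted p = 2.24e-05, 0.802 with estimated correlation). All 13 antigen presentation genes had higher means, none passing by either count, with B2m at 0.92, H2-Eb1 at 3.36 and Psmb9 at 1.37 (adjusted p = 0.000112, 0.842 with estimated correlation). Of 25 neuron genes, 24 had lower means, none passed over all genes and 1 fell when adjusted over the list alone, with Syn1 at -1.18 and Grin2a at -1.04 (adjusted p = 0.000346, 0.878 with estimated correlation). Of 16 myelin genes, 13 had higher means and none passed by either count, with Ugt8a at 1.43, Myrf at 1.69 and Mog at 1.56 (adjusted p = 0.000801, 0.842 with estimated correlation). The gene count was 3, 56, 4 and 5 without R108K libraries 1 to 4, 5 and 2 without mCherry library 2 or 3, 6 with edgeR, 203 with DESeq2, 2 with a term for 2 ranges, 0 within library numbers below 20 (2 libraries against 2, limma, 1730 at an unadjusted p under 0.05) and 9 without the high Met libraries. Neu4 lost its call in 3 of 20 alternatives (adjusted p up to 0.241), none of them the removal of a single library, and the neuron and antigen presentation lists were lost without mCherry library 1 (adjusted p = 0.418 and 0.254) and the myelin list without mCherry library 2 (0.111) or the high Met libraries (0.12) and with library weights (0.0686).

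R222C, another change in the extracellular part, was compared with mCherry, and no gene passed. Neu4 was 29.9 ± 10.3 RPM against 4.10 ± 2.43 RPM (n = 3 each), a log2 difference of 2.68 ± 0.49 SE with a limma adjusted p of 0.0828. Iapp, the islet amyloid gene, was at 7.63 ± 4.93 against 0.114 ± 0.143 RPM (2.75 ± 0.48, adjusted p = 0.0716) and the cytochrome gene Cyp2j9 at 138 ± 13.8 against 36.8 ± 12.8 RPM (1.94). The lowest p among lower genes belonged to Ip6k2 (-0.95), Ttc5 (-1.05) and Zfp609 (-0.90). With limma 1124 genes had an unadjusted p under 0.05, edgeR gave 0 passing genes and DESeq2 95. Egfr was at 3.85 ± 1.09 with an adjusted p of 0.346.

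The lists that passed numbered 5 of 27. All 25 neuron genes had lower means, such as Slc17a6 at -1.40, Nefm at -1.79 and Nefl at -1.62 (camera adjusted p = 7.18e-06, 0.842 with estimated correlation), none passing by either count. Of 16 extracellular matrix genes, 15 had higher means, such as Postn at 3.603, Col4a2 at 1.71 and Hspg2 at 1.72 (adjusted p = 5.14e-05, 0.839 with estimated correlation), none passing by either count. Of 17 OPC genes, none passed over all genes and 2 rose when adjusted over the list alone, with Cspg4 at 1.71 and Cacng4 at 0.86 (adjusted p = 0.0109, 0.842 with estimated correlation). Of 18 astrocyte genes, none passed over all genes and 2 rose when adjusted over the list alone, with Aldoc at 1.63, S100b at 1.78 and Fgfr3 at 1.56 (adjusted p = 0.0351, 0.876 with estimated correlation). The gene count was 3 without R222C library 1, 1 without mCherry library 2 and 8 without the high Met libraries, and no range of library numbers held both groups. The neuron list was lost without mCherry library 1 (adjusted p = 0.125), as was the matrix list (0.0649). The OPC list was lost without mCherry library 2 (0.626), R222C library 1 (0.1) or the high Met libraries (0.647) and reversed with a term for 3 ranges (0.79). The astrocyte list was lost without mCherry library 2 (0.626) or 3 (0.109) or R222C library 1 (0.141) or 3 (0.224), with a term for 2 or 3 ranges (0.11 and 0.374), without the high Met libraries (0.582), and with library weights (0.0553), DESeq2 (0.0587) or only these groups (0.0563).

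T263P, a further extracellular change, was compared with mCherry, and 1 gene rose. Neu4 was 64.2 ± 25.7 RPM against 4.10 ± 2.43 RPM (n = 3 each), a log2 fold change of 3.73 ± 0.49 SE (limma adjusted p = 0.000821). These comparisons of Neu4 all used the same 3 mCherry libraries, and normal cortex had 15.4 ± 0.0825 RPM (n = 2). Of 878 genes with an unadjusted p under 0.05, no other passed, while edgeR gave 1 gene and DESeq2 47. Egfr was at 2.82 ± 1.09 with an adjusted p of 0.877. Of 25 neuron genes, 24 had lower means, such as Syt1 at -2.22, Slc17a6 at -1.37 and Stmn2 at -1.98 (camera adjusted p = 1.3e-08, 0.842 with estimated correlation), none passing by either count.

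Of 16 myelin genes, 15 had higher means with T263P, such as Cnp at 1.61, Ugt8a at 1.44 and Mog at 1.93 (camera adjusted p = 3.68e-07, 0.802 with estimated correlation), none passing by either count. Of 17 OPC genes, Neu4 rose over all genes and 2 did when adjusted over the list alone, with Gpr17 at 2.25 and Cacng4 at 0.86 (adjusted p = 7.27e-07, 0.802 with estimated correlation). All 16 cholesterol synthesis genes had higher means, such as Hmgcs1 at 0.68, Dhcr7 at 0.63 and Srebf2 at 0.58 (adjusted p = 2.24e-05, 0.802 with estimated correlation), none passing by either count. The lists that passed were 9 of 27. Without T263P library 1 the neuron, myelin and cholesterol lists were lost (adjusted p = 0.0839, 0.121 and 0.0872), as were the myelin list with library weights (0.123) and the OPC list with a term for 3 ranges (0.149). Counts were 2 without mCherry library 1, 3 without mCherry library 2, 2 without T263P library 2 and 7 without the high Met libraries. Neu4 lost its call with a term for 3 ranges (adjusted p = 0.999, no gene passing with limma, 504 at an unadjusted p under 0.05) and with only these groups in the fit (0.535), passing in 16 of 18 alternatives, and no range of library numbers held both groups.

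A289I was compared with wild-type EGFR to ask what the changed receptor does beyond the unaltered one. Neu4 rose from 21.7 ± 14.6 RPM (n = 3) to 98.0 ± 38.0 RPM (n = 5), and Nfasc, which encodes a cell adhesion protein of axons and glia, from 139 ± 62.1 to 633 ± 189 RPM. Rpa3, of the single-strand binding complex of DNA replication, fell from 41.9 ± 8.60 to 14.97 ± 2.60 RPM. In all, 35 genes rose and 18 fell. The rises were led by Tmprss3 (log2 2.97 ± 0.63 SE, limma adjusted p = 0.0476), Chil1 (2.60), Lgi3 (2.48), Ppp1r14a (2.32), Neu4 (2.25 ± 0.44, adjusted p = 0.0476), Nfasc (2.22), Map6d1 (2.07) and Pcdhb4 (2.06 ± 0.34, adjusted p = 0.0229). The falls were led by Clec4n (-2.27), Cenpk (-1.77), Psmc3ip (-1.57 ± 0.27, adjusted p = 0.0268), Abracl (-1.44), Rpa3 (-1.43), Sh3bgrl (-1.33) and Hn1 (-1.25). Egfr was at 1.36 ± 0.98 with an adjusted p of 0.58.

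All 16 myelin genes had higher means with A289I, none passed over all genes and 15 rose when adjusted over the list alone, with Myrf at 2.36, Mag at 2.98 and Mog at 2.60 (camera adjusted p = 1.57e-11, 0.802 with estimated correlation). All 30 cell cycle genes had lower means, none passing by either count, with Nusap1 at -1.05, Pcna at -0.70 and Cenpf at -0.99 (adjusted p = 1.93e-08, 0.842 with estimated correlation). Of 18 astrocyte genes, none passed over all genes and 3 rose when adjusted over the list alone, with Atp1b2 at 1.23, Aldoc at 1.15 and Glul at 1.06 (adjusted p = 7.67e-07, 0.802 with estimated correlation). All 25 neuron genes had higher means, none passing by either count, with Vip at 1.42, Syn2 at 1.201 and Nefm at 1.48 (adjusted p = 1.73e-05, 0.842 with estimated correlation). In all, 7 of 27 lists passed. No range of library numbers held both groups, and the gene count was 9 with a term for 2 ranges (all down), 332 with DESeq2, 2 with the neuron covariate, 0 with only these groups in the fit (limma, 1971 at an unadjusted p under 0.05) and 36 without the high Met libraries (5 libraries against 1, 8 up and 28 down), which ended the astrocyte call (0.0747). Of the 16 named genes called, none kept its call with the 2-range term or without the high Met libraries. The count was 125, 1, 0, 1 and 2 without A289I libraries 1 to 5 and 0 without EGFR wild-type library 1 or 2, and the neuron list was lost without EGFR wild-type library 2 (adjusted p = 0.0827).

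A289V differed from wild-type EGFR in 2160 genes, of which 1534 rose and 626 fell. Neuronal genes rose, such as Slc17a7, a vesicular glutamate transporter, from 121 ± 94.2 RPM with the wild-type receptor (n = 3) to 1268 ± 817 RPM (n = 4), the calcium sensor gene Hpca from 42.4 ± 44.5 to 396 ± 221.8 RPM and the neuropeptide gene Cck from 20.5 ± 14.7 to 219 ± 123 RPM. S100a10 fell from 222.3 ± 106 to 30.3 ± 7.28 RPM (log2 -2.73 ± 0.37 SE, limma adjusted p = 0.0015). The largest rises were Vit (4.60 ± 1.02, adjusted p = 0.00975), Hpca (4.06), Car10 (3.93), Slc17a7 (3.84), Trank1 (3.75), Fam163b (3.72), Cck (3.58) and Wipf3 (3.55). The largest falls were Morc1 (-3.97), the retinaldehyde dehydrogenase gene Aldh1a3 (-3.22), Col6a5 (-3.22), the imprinted RNA H19 (-3.20), Hhat (-2.82), Clec4n (-2.76), S100a10 and Tinagl1 (-2.65). Morc1 lay in a stretch of chromosome 16 where 25 neighbouring genes had a median of 1.62 above the tumours' median on the log2 scale in EGFR wild-type library 3. Egfr was at 0.02 ± 1.02 with an adjusted p of 0.992.

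Of the 25 neuron genes, 21 rose and all 25 did when adjusted over the list alone, among them Grin2a (2.79), Vip (2.87) and Slc17a6 (2.52) (camera adjusted p = 8.52e-14, 0.839 with estimated correlation). The neuron list means were 5.47, 3.00 and 4.45 in EGFR wild-type libraries 1 to 3 and 6.26 to 8.10 in the A289V libraries. Of 30 cell cycle genes, 14 fell and 26 did when adjusted over the list alone, among them Nusap1 (-1.56), Pcna (-0.98) and Ube2c (-1.36) (adjusted p = 9.25e-12, 0.839 with estimated correlation). Of 20 mesenchymal glioma genes, 4 fell and 1 rose, and 5 fell and 1 rose when adjusted over the list alone, with S100a11 (-1.76) and Vim (-1.65) falling and Chil1 (2.20) rising (adjusted p = 0.00017, 0.842 with estimated correlation). Of 18 astrocyte genes, 6 rose and 9 did when adjusted over the list alone, among them Gjb6 (3.18), Aldoc (1.26) and Glul (1.04) (adjusted p = 0.000203, 0.842 with estimated correlation). In all, 11 of 27 lists passed. The gene count was 589 without A289V library 1, 128 without A289V library 2 and 78 without EGFR wild-type library 2, 1 without A289V libraries 1 and 2, and 33 without the high Met libraries (4 libraries against 1, 8 up and 25 down). That removal and the neuron covariate ended the mesenchymal (adjusted p = 0.792 and 0.0594) and astrocyte (0.075 and 0.299) calls. The count was 0 with the neuron covariate (limma, 797 at an unadjusted p under 0.05), 26 within the range 20 to 37 (3 libraries against 1, 3 up and 23 down) and 4 below 20 (1 against 2), against 1879 with edgeR and 2900 with DESeq2 in all libraries. Of the 28 named genes called, 1 kept its call without the high Met libraries and 1 within 20 to 37.

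No gene passed between R108G and wild-type EGFR with limma, while 1347 had an unadjusted p under 0.05, edgeR gave 0 and DESeq2 95. Neu4 was 105.5 ± 27.8 against 21.7 ± 14.6 RPM (n = 3 each), a log2 difference of 2.42 ± 0.49 SE (adjusted p = 0.292), the connexin gene Gjb2 6.39 ± 2.17 against 0.921 ± 0.817 RPM, and Ppfia1 179 ± 102 against 70.5 ± 9.28 RPM. C1d was at -1.10, Mir684-2 at -2.14 and the translation initiation gene Eif4e at -1.13. Egfr was at -1.24 ± 1.09 with an adjusted p of 0.754. All 18 astrocyte genes had higher means, none passed over all genes and 4 rose when adjusted over the list alone, with Atp1b2 at 1.24, Gja1 at 2.29 and Gjb6 at 2.06 (camera adjusted p = 8.18e-08, 0.802 with estimated correlation). All 25 neuron genes had higher means, none passing by either count, with Nefl at 1.87, Nefm at 1.87 and Vip at 1.42 (adjusted p = 1.08e-05, 0.842 with estimated correlation). Of 17 vessel genes, 16 had higher means, none passing by either count, with Vwf at 1.23, Kdr at 1.09 and Esam at 0.85 (adjusted p = 4.92e-05, 0.839 with estimated correlation). All 6 B and plasma cell genes had higher means, none passed over all genes and 1 rose when adjusted over the list alone, with Cd79a at 1.93 and Cd79b at 0.94 (adjusted p = 0.000961, 0.842 with estimated correlation). In all, 10 of 27 lists passed. No range held both groups, and the gene count was 5 with a term for 2 ranges, which also reversed the vessel list (adjusted p = 0.741) and ended the B cell call (0.934), as did 3 ranges (0.963 and 0.87). The count was 6 without R108G library 1, 3 without EGFR wild-type library 3, 7 without R108G libraries 1 and 3 (1 library against 3), and 23 without the high Met libraries (3 against 1), where the vessel list was lost.

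Between R108K and wild-type EGFR no gene passed with limma, 861 had an unadjusted p under 0.05, edgeR gave 0 and DESeq2 60. Phf7 was 11.7 ± 1.74 RPM (n = 4) against 4.45 ± 1.36 RPM (n = 3), a log2 difference of 1.25 ± 0.26 SE (adjusted p = 0.46), Bfsp2 163 ± 53.3 against 26.7 ± 17.7 RPM, and Cgrrf1 44.4 ± 27.3 against 14.4 ± 5.01 RPM. Efnb1 was at -1.35, Mboat1 at -1.19 and the signalling ligand Wnt6 at -1.30. Egfr was at 0.35 ± 1.02 with an adjusted p of 0.987. All 6 B and plasma cell genes had higher means, such as Cd79a at 1.99, Mzb1 at 2.48 and Jchain at 2.64 (camera adjusted p = 4.41e-05, 0.802 with estimated correlation). Of 20 interferon genes, 19 had higher means, such as Ifit3 at 1.60, Mx2 at 1.69 and Irf7 at 1.58 (adjusted p = 9.5e-05, 0.842 with estimated correlation). Of 20 genes of MAPK output, which follow signalling through ERK, 17 had lower means, such as Spred2 at -0.94, Etv4 at -1.35 and Spred1 at -0.56 (adjusted p = 0.00116, 0.842 with estimated correlation). Of 13 antigen presentation genes, 12 had higher means, such as H2-K1 at 0.83, H2-D1 at 0.84 and Tap1 at 0.89 (adjusted p = 0.00956, 0.876 with estimated correlation). No member of these 4 lists passed over all genes or adjusted over the list alone, and 5 of 27 lists passed. The gene count was 25 without the high Met libraries (4 libraries against 1), 23 within the range 20 to 37 (2 libraries against 1), 2 within the range below 20 (2 against 2), 2 without EGFR wild-type library 3 and 1 without R108K library 3. The MAPK list reversed without the high Met libraries (adjusted p = 0.164) and was lost without EGFR wild-type library 2 (0.88) or R108K library 3 (0.0843). The interferon list was lost without EGFR wild-type library 3 (0.949), and the antigen list without EGFR wild-type library 2 (0.418) or 3 (0.0792), R108K library 3 (0.171) or the high Met libraries (0.0523) and with library weights (0.095).

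R222C and wild-type EGFR likewise differed in no gene with limma, 796 had an unadjusted p under 0.05, edgeR gave 0 and DESeq2 33. Cyth3 was 66.6 ± 15.3 against 28.8 ± 2.63 RPM (n = 3 each), a log2 difference of 1.16 ± 0.25 SE (adjusted p = 0.615), Spaca1 3.92 ± 2.62 against 0.319 ± 0.368 RPM, and Colgalt2, a collagen galactosyltransferase, 23.2 ± 16.1 against 4.92 ± 1.19 RPM. Cdv3 was at -1.20, Exog at -0.99 and Hebp2 at -1.59. Egfr was at 1.02 ± 1.09 with an adjusted p of 0.999. Of 18 astrocyte genes, 16 had higher means, none passed over all genes and 2 rose when adjusted over the list alone, with Aldoc at 1.36, Atp1b2 at 1.03 and Glul at 0.91 (camera adjusted p = 3.58e-05, 0.839 with estimated correlation). Of 20 interferon genes, 18 had higher means, such as Oas2 at 1.87, Ifit3 at 1.48 and Oasl2 at 1.34 (adjusted p = 0.000599, 0.873 with estimated correlation). Of 16 matrix genes, 14 had higher means, such as Lamc1 at 1.16, Hspg2 at 1.22 and Postn at 2.23 (adjusted p = 0.00204, 0.842 with estimated correlation). Of 30 cell cycle genes, 25 had lower means, such as Tpx2 at -0.63, Nusap1 at -0.63 and Ccnb2 at -0.75 (adjusted p = 0.00272, 0.903 with estimated correlation). No interferon, matrix or cell cycle gene passed over all genes or adjusted over the list alone, and 4 of 27 lists passed. The gene count was 32 without the high Met libraries (3 libraries against 1), 29 within the range 20 to 37 (3 libraries against 1), 2 without EGFR wild-type library 3 and 1 without R222C library 1. The interferon list reversed without R222C library 3 (adjusted p = 0.969) or EGFR wild-type library 3 (0.89) and was lost with library weights (0.636). The cell cycle list was lost without EGFR wild-type library 1 (0.0572) or R222C library 2 (0.243) or 3 (0.147), without the high Met libraries (0.897), as the astrocyte list was (0.32), and with DESeq2 (0.0533). The matrix list was lost without EGFR wild-type library 2 (0.0769) or R222C library 2 (0.072) and with library weights (0.0851).

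For T263P and wild-type EGFR no gene passed with limma, 622 had an unadjusted p under 0.05, edgeR gave 0 and DESeq2 38. Met was 4.26 ± 2.01 RPM in the T263P tumours against 2822 ± 2470 RPM with the wild-type receptor (n = 3 each), a log2 difference of -6.44 ± 2.23 SE (adjusted p = 1) that rested on EGFR wild-type libraries 1 and 2 and was 0.14 without the high Met libraries. Phf7 was 11.4 ± 3.69 against 4.45 ± 1.36 RPM, Zcchc24 342 ± 155 against 130 ± 41.6 RPM and the adaptor gene Efs 168 ± 46.1 against 63.3 ± 30.5 RPM, and Hebp2 was at -1.93, Wnt6 at -1.30 and Morc1 at -4.60. Egfr was at -0.01 ± 1.09 with an adjusted p of 1. Of 20 mesenchymal glioma genes, 19 had lower means, such as Vim at -1.15 and Anxa1 at -1.77 (camera adjusted p = 1.31e-09, 0.802 with estimated correlation). Of 17 OPC genes, 15 had higher means and 1 rose when adjusted over the list alone, with Neu4 at 1.67, Ptprz1 at -1.38 and Gpr17 at 1.34 (adjusted p = 0.000801, 0.842 with estimated correlation). Of 20 MAPK output genes, 18 had lower means, such as Spred3 at -1.11, Dusp6 at -1.34 and Fosl1 at -0.80 (adjusted p = 0.000854, 0.842 with estimated correlation). Of 20 genes of hypoxia and glycolysis, 18 had lower means, such as Pfkfb4 at -0.74, Slc2a1 at -0.60 and Bnip3 at -0.73 (adjusted p = 0.00335, 0.842 with estimated correlation). No other member of these 4 lists passed over all genes or adjusted over the list alone, and 7 of 27 lists passed. All 4 lists reversed without the high Met libraries (adjusted p = 0.874, 0.802, 0.13 and 0.732), which left EGFR wild-type library 3 alone and gave 21 genes, against 25 within the range 20 to 37 (3 libraries against 1), 2 without EGFR wild-type library 3 and 1 without T263P library 2. The MAPK list was also lost without EGFR wild-type library 2 (0.876) and the OPC list without EGFR wild-type library 1 (0.221). The hypoxia list was lost without EGFR wild-type library 2 (0.166) or T263P library 2 (0.693) or 3 (0.0937) and with DESeq2 (0.0663). With a term for 3 ranges the MAPK, OPC and hypoxia lists were lost (0.321, 0.855 and 0.508).

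A289I and A289V, which differ in the amino acid put in place of the same alanine, were compared directly, and no gene passed with limma (2872 at an unadjusted p under 0.05, edgeR 0, DESeq2 221). Ermard was 71.8 ± 35.05 RPM with A289I (n = 5) against 25.99 ± 7.03 RPM with A289V (n = 4), a log2 difference of 1.36 ± 0.28 SE (adjusted p = 0.0755), Cc2d1b 58.5 ± 11.2 against 31.2 ± 3.92 RPM and Cdr2l 79.1 ± 19.8 against 31.2 ± 7.17 RPM. The steroid dehydrogenase gene Akr1c18 was at -1.62, Cfap57 at -0.92 and Kctd16 at -1.61. Egfr was at 1.34 ± 0.90 with an adjusted p of 0.446. All 25 neuron genes had lower means with A289I, none passed over all genes and 19 fell when adjusted over the list alone, with Grin2a at -1.97 and Slc17a6 at -1.65 (camera adjusted p = 1.18e-11, 0.839 with estimated correlation). Of 20 mesenchymal glioma genes, 19 had higher means, none passed over all genes and 2 rose when adjusted over the list alone, with Vim at 1.18, S100a11 at 0.95 and Tnc at 2.69 (adjusted p = 9.81e-06, 0.842 with estimated correlation). All 30 cell cycle genes had higher means, none passing by either count, with Cdc20 at 1.05, Aurka at 0.70 and Birc5 at 0.63 (adjusted p = 1.22e-05, 0.842 with estimated correlation). All 16 T and NK cell genes had higher means, none passing by either count, with Nkg7 at 1.68, Lck at 1.31 and Cd3e at 1.27 (adjusted p = 0.000206, 0.842 with estimated correlation), and A289I library 2 had the highest level of these 3 genes in its group. In all, 13 of 27 lists passed. No range of library numbers held both groups, and the gene count was 4 with a term for 2 ranges, which reversed the cell cycle list (adjusted p = 0.84) and ended the T and NK call (0.547). With 3 ranges these lists and the mesenchymal list were lost (0.47, 0.605 and 0.446), and the cell cycle list was lost without A289V libraries 1 and 2 (0.775) or with the neuron covariate (0.0652). The count was 534 without A289I library 4, 1, 14 and 172 without A289V libraries 2, 3 and 4, and 3241 with library weights.

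R108G and R108K, which differ in the amino acid put in place of the same arginine, were compared directly, and no gene passed with limma (1569 at an unadjusted p under 0.05, edgeR 0, DESeq2 112). Plxdc2 was 43.9 ± 17.2 RPM with R108G (n = 3) against 10.9 ± 3.58 RPM with R108K (n = 4), a log2 difference of 1.90 ± 0.33 SE (adjusted p = 0.0657), the lipid transporter gene Abca3 120 ± 22.98 against 63.0 ± 7.63 RPM and Aspg 25.6 ± 11.1 against 5.61 ± 4.55 RPM. Rab28 was at -0.96, C1d at -1.17 and Mir684-2 at -2.08. Egfr was at -1.59 ± 1.02 with an adjusted p of 0.605. All 18 astrocyte genes had higher means, none passed over all genes and 7 rose when adjusted over the list alone, with Gja1 at 2.32, Slc1a2 at 2.01 and Slc1a3 at 1.26 (camera adjusted p = 6.34e-07, 0.802 with estimated correlation). All 25 neuron genes had higher means, such as Syn1 at 1.84 and Slc17a7 at 2.32 (adjusted p = 4.66e-06, 0.842 with estimated correlation). Of 20 synapse-promoting genes, 17 had higher means, such as Tenm2 at 1.201, Bdnf at 2.01 and Gpc4 at 1.24 (adjusted p = 0.00202, 0.802 with estimated correlation). All 12 immediate early genes had higher means, such as Arc at 2.29, Egr1 at 1.13 and Fos at 0.93 (adjusted p = 0.00792, 0.842 with estimated correlation). No neuron, synapse-promoting or immediate early gene passed over all genes or adjusted over the list alone, and 6 of 27 lists passed. No range of library numbers held both groups, and the gene count was 4 with a term for 2 ranges, 3 with library weights, 15 and 2 without R108G library 1 or 2, 7 and 9 without R108K library 3 or 4, and 8 without R108G libraries 1 and 3 (1 library against 4). The immediate early list was lost without R108G library 2 (adjusted p = 0.152).

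Across the 8 tumour groups, an F-test asked whether any group stood apart, without a choice of pair. Of the 15824 genes, 1633 passed, and A289V had the highest or lowest group mean in 82.5% of them, highest in 1079 and lowest in 268. Neu4 had the smallest p (adjusted p = 0.000154), with group means from 4.10 RPM with mCherry to 105.5 RPM with R108G. Most of the next genes were highest in A289V: the synaptic vesicle gene Sv2a (284 RPM there against 28.9 RPM in R222C), Ak5 (134 against 11.4 RPM in R108K), Ank (232 against 78.2 RPM in EGFR wild type), Plcl1 (33.1 against 8.44 RPM in R222C), Pde4a (82.3 against 8.98 RPM in T263P), Mfsd4 (31.4 against 4.93 RPM in R108K), Mink1 (430.5 against 93.2 RPM in mCherry) and Lppr2 (140 against 23.4 RPM in R222C). The same held for Pi4ka, Map1a, Tenm2, Atp2b4, Gjb2 and Pcdha12, whereas Aspg and Abca3 were highest in R108G. S100a10 (222.3 RPM in EGFR wild type against 30.3 RPM in A289V), Tbca (124 against 61.1 RPM in A289I) and Snrpe (109 against 42.5 RPM in A289V) were highest in the EGFR wild-type tumours. With DESeq2 4222 genes passed, with library weights 5876 and with a term for 3 ranges 1083, while the count was 216 without A289V library 1, 229 without A289V library 2, 2 without both and 3 with the neuron covariate. Of these 20 genes only Neu4 kept its call without A289V libraries 1 and 2 and with the neuron covariate, and it passed in all 42 alternatives with an adjusted p of at most 0.00394.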

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

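The tests chosen after the result was seen were those of depth and of a gain of chromosome 6 for Met, of a wrong cortex label and of an effect in every tumour for A289V, of a wrong mCherry label, an exchange and a lower transcript in every tumour for R108G, and the splits of the samples. In groups of 4 or 5 libraries, a value far from the others of its group was found in 18 of 206 groups of values, where chance gives about 1 in 20. In A289I library 3 Col9a3 was 418.2 RPM (next 188.8). In A289I library 1 S100b was low at 130.4 RPM (next 273.3), and Cdk1 was 109.6 (next 45.99), Nusap1 65.9 (next 34.05) and Pcna 177.6 RPM (next 117.6). A289I library 5 had Ermard at 131.7 RPM (next 64.1). A289I library 2 had Nkg7 at 17.11 (next 4.579), Lck at 23.42 (next 10.24) and Cd3e at 10.03 RPM (next 2.467), and a mean of the T and NK cell list of 3.225 on the log2 scale (next 1.886). In A289V library 3 Dct was 92.69 (next 10.67) and Tex19.1 0.1769 RPM (0 in the next). In A289V library 4 Srebf2 was low at 181.6 (next 319) and Akr1c18 at 0.6161 RPM (next 4.625). In R108K library 2 Pllp was low at 155.9 (next 411.3) and Prr14 at 48.45 RPM (next 69.96). R108K library 1 had Ugt8a at 177.9 (next 94.56) and H2-D1 at 3270 RPM (next 1518).

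Met was 4610, 3853 and 6283 RPM in EGFR wild-type libraries 1 and 2 and mCherry library 2. Depth or normalisation was argued against: as shares of recovered reads, free of size factors, Met and its 9 neighbours within 1 Mb had medians at least 1.15 above the tumour median (log2). So was 1 source of RNA in all 3: the Capza2 excess over that of Met was 0.617, 0.184 and 0.172 (highest over lowest 3.59). A shared source for EGFR wild-type and mCherry library 2 stayed open on Capza2, but St7 lay 0.18 and 1.52 and Cttnbp2 -0.36 and 1.14 from the tumour median. A gain of the stretch around Met stayed open: its neighbours alone had medians 1.17, 0.89 and 1.86 above the tumour median, with 9, 8 and 8 above it. DNA copy number was not measured, and no biological explanation was tested.

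The A289V tumours had high neuron and low cell cycle means, most in libraries 1 and 2. Cortex under an A289V label was argued against, since the cell cycle mean of the lower library lay 2.8 above the highest cortex library on the log2 scale. More normal cortex in the pieces taken may account for part of it: neuron genes implied a cortex share of 53.7% and 72.4% in libraries 1 and 2, myelin genes 24.3% and 41.8% (lower ratio 0.453, between the bounds set) and astrocyte genes 36.9% and 49.0%. In libraries 3 and 4 all 3 lists gave 10.5% to 18.4%. An effect of A289V in every tumour also stayed open: the lowest A289V library had a neuron mean 0.79 above the highest EGFR wild-type library, but at 6.26 it lay below the highest mCherry (6.39) and A289I (6.77) libraries. Its first form, replaced once seen, was the gene count without libraries 1 and 2 (1 against EGFR wild type).

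Egfr was 17.5 and 52.3 RPM in R108G libraries 1 and 3. An exchange with mCherry libraries was argued against, since none of these, at up to 35.4 RPM, reached another receptor tumour. mCherry tumours from outside under an R108G label stayed open: on 50 genes picked without R108G libraries (0, the mCherry mean, 1, that of the other receptor groups) the lower one was placed at -0.06 from the highest mCherry library left out of the pick, but such mCherry libraries (0.691 to 1.01) did not part from receptor tumours (0.206 to 1.44). Neu4 was 112.2 and 129.3 RPM in R108G libraries 1 and 3 and 1.59 to 6.44 in mCherry, and Col9a3, S100a1 and Pllp were also higher, but these genes were picked on the mCherry libraries. Too few reads did not account for it, since the higher of the upper 95% bounds was 56.1 RPM, below the lowest EGFR wild-type library (115 RPM). A lower transcript in every R108G tumour was argued against by 732 RPM in library 2. Loss of the introduced gene, or its expression from a sequence that mouse Egfr does not count, was not tested.

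Other splits of the same libraries were run for 16 counts. The share of splits as large, unadjusted over the 16, was under 0.05 for A289I against mCherry (96 genes, highest other split 1, 1 of 56), A289I against EGFR wild type (53, other 22, 1 of 56), A289V against EGFR wild type (2160, other 1733, 1 of 35) and any difference (1633, other 2, 1 of 100). That does not part variant from library number: all 5 A289I libraries were above 37, with 1 mCherry and no EGFR wild-type library. Nor does the term for 2 ranges, set by mCherry library 3 against libraries 1 and 2. Chance cannot be excluded for A289V (777, other 1135, 2 of 35) or R108K (11, other 205, 6 of 35) against mCherry. For R108K, a split calling several times the real count points to a structure of the samples. Where the real count was 0 every split gives as many, so nothing about chance follows: R108K against EGFR wild type (other 482, 35 of 35), A289I against A289V (other 677, 100 of 100) and R108G against R108K (other 16, 35 of 35). The 10 splits of 3 against 3 were too few for a share under 0.05: against mCherry the real and highest other counts were 0 and 351 for EGFR wild type, 6 and 1 for R108G, 0 and 6 for R222C, and 1 and 26 for T263P (5 of 10 as large). Against EGFR wild type they were 0 and 3 for R108G, 0 and 0 for R222C, and 0 and 434 for T263P. The splits with 351, 482, 677, 434, 1733 and 1135 genes also point to a structure of the samples.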

How the results depend on the processing

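Chosen after seeing the data were the 3-range term, groups within 1 range and the neuron covariate. Removal of the high Met libraries, R108G libraries 1 and 3 or A289V libraries 1 and 2 was too. No paired analysis was possible: replicates were numbered only by order of deposition and every library number was unique. Over the named genes and all other settings than single libraries left out, 3986 values kept their direction and side of the threshold, 693 lost a call, 105 gained one and 35 changed sign. With single libraries left out these were 2452, 430, 36 and 10. For the described lists they were 744 kept, 175 lost and 10 reversed, and 391, 44 and 3 with single libraries left out. Each count is of genes past the threshold by limma unless another tool is named. Where a result was lost or turned, the cause was not tested.

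Without a filter the count was 44 for A289I, 437 for A289V and 7 for R108K against mCherry, 5 for A289I against EGFR wild type and 7 for A289I against A289V. With a pseudocount of 0.1 RPM it was 403 for A289V against mCherry and 22 for A289I against EGFR wild type. With library weights it was 325 for A289I, 3101 for A289V, 54 for R108G, 2 for R108K and 3 for R222C against mCherry, 456 for A289I, 4448 for A289V and 71 for R108G against EGFR wild type, 3241 for A289I against A289V, 3 for R108G against R108K and 5876 for any difference. With only the groups compared in the fit it was 42 for A289I, 3 for A289V, 0 for R108G (1123 at an unadjusted p under 0.05), 2 for R108K and 1 for R222C against mCherry, 0 for A289I (1971) and 937 for A289V against EGFR wild type, and 1 for A289I against A289V. With edgeR it was 1 for A289I, 3.0e+02 for A289V and 6 for R108K against mCherry. With DESeq2 it was 10 for EGFR wild type, 349 for A289I, 1729 for A289V, 98 for R108G, 203 for R108K, 95 for R222C and 47 for T263P against mCherry. Against EGFR wild type DESeq2 gave 332 for A289I, 95 for R108G, 60 for R108K, 33 for R222C and 38 for T263P. It gave 221 for A289I against A289V, 112 for R108G against R108K and 4222 for any difference.

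With a term for 2 ranges the count was 16 for A289I, 2 for A289V, 10 for R108G and 2 for R108K against mCherry, 9 for A289I and 5 for R108G against EGFR wild type, and 4 for A289I against A289V as for R108G against R108K. With a term for 3 ranges it was 3867 for mCherry against cortex, 16 for A289I, 0 for A289V (2675 at an unadjusted p under 0.05), 11 for R108G, 0 for R108K (1396) and 0 for T263P (504) against mCherry, 10 for A289I and 7 for R108G against EGFR wild type, 3 for A289I against A289V and 1083 for any difference. Within library numbers below 20 it was 1 for EGFR wild type, 2 for A289V and 0 for R108K (1730) against mCherry, and 4 for A289V and 2 for R108K against EGFR wild type. Within 20 to 37 it was 26 for A289V, 23 for R108K, 29 for R222C and 25 for T263P against EGFR wild type, and above 37 it was 21 for A289I and 15 for R108G against mCherry. With the neuron covariate it was 1662 for mCherry against cortex, 1 for A289V and 7 for R108K against mCherry, 2 for A289I and 0 for A289V (797) against EGFR wild type, and 3 for any difference. Without the high Met libraries, which leaves 1 EGFR wild-type library, it was 21 for EGFR wild type and for A289I, 46 for A289V, 14 for R108G, 8 for R222C and 7 for T263P against mCherry, and 33 for A289V, 23 for R108G, 25 for R108K, 32 for R222C and 21 for T263P against EGFR wild type. Without A289V libraries 1 and 2 it was 1 for A289V against either control and 2 for any difference, and without R108G libraries 1 and 3, which leaves 1, it was 13 for R108G against mCherry, 7 against EGFR wild type and 8 against R108K.

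With each library of the groups left out in turn the count was 3280 to 6050 for mCherry against cortex, where the lone cortex library left was assumed to vary like the other groups. Against mCherry it was 0 to 1 for EGFR wild type, 1 to 162 for A289I, 2 to 1674 for A289V, 1 to 10 for R108G, 2 to 56 for R108K, 0 to 3 for R222C and 1 to 3 for T263P. Against EGFR wild type it was 0 to 125 for A289I, 78 to 2563 for A289V, 0 to 6 for R108G and 0 to 2 for R108K, R222C and T263P. It was 0 to 534 for A289I against A289V, 0 to 15 for R108G against R108K and 216 to 2103 for any difference. Egfr against mCherry passed in 0 of 7 comparisons without a filter, with either range term, without the high Met libraries, with edgeR and with any single mCherry library left out, and in 4 with DESeq2. Of the list calls, 0 held with an estimated correlation and 19 in fry.

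Signs turned as follows, in values on the log2 scale, none of which passed. Egfr in R108G against EGFR wild type was 0.162 with DESeq2, 0.146 with edgeR, 0.471 with library weights and 1.788 without R108G libraries 1 and 3, which gave 1.437 against R108K. Egfr in T263P against EGFR wild type was 0.716 with DESeq2, 0.733 with edgeR, 0.092 with library weights, 0.001 with TMM, 0.025 with 3 ranges and -1.09 to 0.982 with single libraries left out. Egfr in A289V was -0.869 without the high Met libraries, -0.949 within 20 to 37 and -0.459 to 0.468 with single libraries left out. Egfr in R108K was -0.541, -0.931 and -0.087 to 0.796 in those settings, and H2-D1 -0.15, -0.418 and -0.051 to 1.329. Egfr in R222C was -0.328 to 2.078 with single libraries left out. In T263P against EGFR wild type Met was 0.138, Anxa1 0.156, Ptprz1 0.16, Dusp6 0.315, Fosl1 0.092 and Bnip3 0.237, both without the high Met libraries and within 20 to 37. Against mCherry, in EGFR wild type, Ccnb1 was -0.162 without the high Met libraries and Oasl2 0.09 within numbers below 20. Cd79b in R108G against EGFR wild type was -0.132 with 2 ranges and -0.138 with 3, and in A289I against A289V Aurka was -0.03 and -0.046 and Cdc20 -0.314 with 2 ranges.

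Of the lists, OPC in R222C against mCherry reversed with 3 ranges (adjusted p = 0.79), vessels in R108G against EGFR wild type with 2 (0.741) and 3 (0.963) and cell cycle in A289I against A289V with 2 (0.84). Without the high Met libraries cell cycle in EGFR wild type against mCherry reversed (0.289), as did MAPK output in R108K (0.164) and T263P (0.13), and in T263P also OPC (0.802), mesenchymal (0.874) and hypoxia (0.732), all against EGFR wild type. At the preset correlation these lists' highest adjusted p was 0.578 to 0.963. With single libraries left out the adjusted p of the interferon list was 4.36e-06 to 0.306 in EGFR wild type against mCherry and 8.91e-08 to 0.969 in R222C against EGFR wild type. Groups of 2 to 5 libraries left small changes unseen, groups and ranges of library numbers overlapped little, and cell types could not be parted in bulk tissue. At the lowest depth 1 read was 0.383 RPM, so levels below it could not be told from 0 in that library.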

Other observations

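Relations and runs of neighbouring genes were tested, and the test of runs was chosen after the result was seen. Besides the lists described above, mCherry tumours differed from cortex in genes of oligodendrocyte precursors and myeloid cells. Of 17 OPC genes, 12 rose and 1 fell, and 13 rose and 1 fell when adjusted over the list alone (camera adjusted p = 9.5e-05). Of 16 genes of monocytes and macrophages, 8 rose by either count, among them the lysozyme gene Lyz2 (4.46 ± 0.62 SE), the galectin gene Lgals3 (4.98), Cd68 (2.22) and Cd14 (2.04) (adjusted p = 0.0035). Of 16 proneural glioma genes, 9 rose and 2 fell, and 10 rose and 4 fell when adjusted over the list alone. The transcription factor genes Sox4 (4.08), Myt1 (3.28) and Olig2 (2.85) rose, and the neuronal tubulin gene Tubb3 (-1.99) fell (adjusted p = 0.032). With an estimated correlation the adjusted p of each of the 3 lists was 0.842.

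Across the 25 tumours given a receptor, the hypothesis that more Egfr transcript goes with more MAPK output was tested as 1 of 4 relations, the others being with the cell cycle list, the OPC list and Neu4. Spearman's rho was 0.35 (permutation p = 0.0924, adjusted 0.37) and Pearson's r 0.35 (permutation p = 0.0915, adjusted 0.366), and r was 0.22 without the 2 libraries farthest from the median. In the range 20 to 37 r was 0.62 (12 tumours, permutation p = 0.0338) and rho 0.36 (permutation p = 0.256). Above 37 r was 0.59 (8 tumours, exact permutation p = 0.114) and rho 0.31 (exact permutation p = 0.462), and below 20 there were only 5 tumours. The other 3 relations had adjusted p of 0.848 to 0.859, and their lowest p within a range was that of Neu4 above 37 (rho -0.74, exact permutation p = 0.0458, r -0.44, exact permutation p = 0.265). Values within ranges were not adjusted. A relation with MAPK output was not shown.

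Whether stretches of raised neighbouring genes in single tumours came from gains of chromosome stretches stayed open. There were 44 runs against at most 24 in 100 permuted gene orders, and 3 exceeded the longest permuted run (17 genes). Permuted orders break the co-expression of neighbours, 20 runs shared genes with a run of another tumour, and 17 lay in A289V libraries 1 and 2, so neither form of the test decides. Among the 3 were runs in EGFR wild-type library 3 on chromosome 16 (39984361 to 55838899, mm10, 25 genes, median 1.62) and in mCherry library 2 on chromosome 6 (13580687 to 23839421, 18 genes with Met and Ptprz1, median 1.56). DNA copy number was not measured.

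Xist was low and Y-linked genes were present in 7 of 30 libraries, all A289I, R108G, R108K or T263P. The labels give no sex. Its part in X-linked Sh3bgrl, Tmsb4x, Zc4h2, Efnb1, Syn1 and Gpc4 was not tested. A289V and mCherry, compared for X-linked Cdr1, Col4a5 and Dach2, held no such library.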
